A study of Mus musculus with 12 samples.

How the data were processed

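Gene expression was measured on 12 one-colour Agilent whole-genome mouse arrays, 1 per sample. The samples were cultures of NIH3T3, an established mouse embryonic fibroblast line, treated for 18 h with the solvent DMSO, with rapamycin or with PP242, with 4 arrays in each of the 3 groups. The series' design text calls the 4 samples of a condition independent experiments. Groups and replicate numbers were taken from the sample titles. The PP242 dose is 2 µM in the design text and in the sample characteristics, whereas the treatment protocol gives 2 mM; 2 µM is used here. Per the labels' protocols, total RNA was purified on Qiagen columns, amplified with a Sigma whole transcriptome kit and labelled with Cy3 using a NimbleGen kit.

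The deposited scanner files hold linear intensity values for 45018 spots per array, per the file headers. Of these, 43379 spots belonged to 41174 probes and 1639 were control spots. The processed signal used here is an intensity that, per the file headers, Agilent Feature Extraction had background-subtracted and detrended within each array, with no scaling between arrays. The file headers name version 10.5.1.1 of that software and the submitters' processing notes name version 10.1, and which of them the notes refer to is not given in the sources used here. The value table deposited for the whole series holds log2 values of the same arrays. Each of its columns had a median near 8.55 (lowest 8.54, highest 8.56) and ranked the probes as that array's median spot intensity did, with a Spearman correlation of at least 0.9998. Its scale is therefore log2 of an intensity without background subtraction, made alike between arrays. The tool behind it is not given in the sources used here, and it was used as an alternative only.

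From the processed intensity the following was computed. Log2 values were taken and each array's 75th percentile over non-control probes was subtracted. Control spots and spots marked as non-uniform or population outliers by the software were left out, which removed 5148 gene values, 1.68% of the matrix. Spots of the same probe were averaged, including 245 probes spotted 10 times. Probes well above background on at least 4 of the 12 arrays, whatever their group, were kept, and each gene was represented by its brightest probe over the 12 arrays. RefSeq accessions of the array design were matched without versions to current mouse symbols: 24812 of 25268 probes with such an accession were matched. In all, 24836 probes had 1 gene symbol, 0 had several and 16338 were known by accession only. The 25581 genes tested include 15116 with a symbol. No saturated spot was found on any array.

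Limma 3.58.1 in R 4.3.3 was used (lmFit and eBayes) on all 12 arrays together, so that the 3 groups share 1 estimate of the spread, with contrasts of rapamycin against DMSO, PP242 against DMSO and PP242 against rapamycin. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Adjusted p-values of single genes are from limma throughout. There were 33 gene lists with 718 genes, covering metabolism, translation, the cell cycle, stress responses, signalling, the matrix and markers of other cell types. Lists with at least 5 measured members were tested with limma's camera at a preset correlation between genes of 0.01, which compares a list with all other genes, and p-values were adjusted over the lists. Camera with an estimated correlation and limma's fry were alternatives. Fry tests whether the genes of a set move, on balance, one way, and does not compare them with other genes. Data were read and drawn with the data.table package (version 1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

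The groups, the tests, the lists, most alternatives and the rule for named genes were fixed before the data were examined. The named genes of a comparison are the 8 largest rises and 8 largest falls among genes with an assigned symbol that passed, were well above background on all arrays and had groups that did not overlap; in each list up to 4 passing members in order of adjusted p and up to 2 that did not pass in order of level; the 3 largest bounds per direction; 12 genes of the pathway whatever their result, of which Irs2 and Ccnd1 are not analysed here; and the 5 largest PP242 changes per direction among genes called in both comparisons of a pair. The alternatives chosen then were quantile normalisation, median centring, the unsubtracted median signal, the deposited log2 table, no filter, a filter on all 12 arrays, the mean of a gene's probes, fits of only the groups compared, slide or replicate number as a block, an intensity trend, array quality weights, other set tests and leaving out each array in turn. Background correction by normexp on the mean spot signal was planned and not run, because the files as used here hold the median spot signal; it was run on that with an offset of 50.

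A set of fits on 8 arrays was added after the data had been seen. It leaves out the 4 arrays on which the 75th percentile of the processed signal was under 100 times the 25th percentile (DMSO 2, rapamycin 3, PP242 1 and PP242 4), a technical criterion, and keeps 3 DMSO, 3 rapamycin and 2 PP242 arrays. The counts of the 12-array fit, and those of 8 arrays with the planned filter, were known before the filter of the reported 8-array fit was chosen: probes well above background on at least 2 of the 8 arrays, 19591 genes. Several versions of the 8-array fit were run and all are given with the alternatives. For each comparison the planned 12-array counts of genes and of lists called are given with those of the 8 arrays, and the rule for named genes was applied to both fits. The group of 2 PP242 arrays holds no array numbered 4, whereas both other groups do.

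The procedure was tested on simulated data in which genes of the comparison of PP242 with DMSO were changed, 50 at each of 4 sizes. On 12 arrays with 25581 genes it recovered 0%, 2%, 26% and 46% of log2 changes of 0.5, 1, 2 and 3, with 0 false calls. On 8 arrays with 19591 genes it recovered 4%, 36%, 60% and 82%, with 2 false calls. These counts hold for the simulated noise, not for deviations that real arrays share. The number of arrays, and on the 4 arrays named above the signal of dim probes, limits the precision. For a probe not well above background on any array of 1 group, a bound was computed as the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal; it is given as "at least N-fold". Only log2 differences of the same probe between groups are compared.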

Results

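Gene expression was measured on 12 one-colour arrays in NIH3T3 cells, a mouse embryonic fibroblast line. Cells had been treated for 18 h with the solvent DMSO, 50 nM rapamycin or 2 µM PP242 (4 arrays each). The treatment protocol instead gives 2 mM PP242. The design text calls the replicates independent experiments. Rapamycin is a macrolide that inhibits mTORC1, 1 of the complexes of the mTOR kinase, allosterically. PP242 competes with ATP in the kinase itself and so acts on both mTORC1 and mTORC2. The series asks which genes are regulated through each of these complexes. The compounds were given at different doses, each at a single dose, so the comparisons between them are between these treatments and not between structures at a matched dose.

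The arrays fell into 2 kinds by signal. On 8 of them, 55.8% to 60.5% of probes were well above background and the 75th percentile of the processed signal was 261 to 420 times the 25th. On the other 4 the dim probes were raised. The share of probes well above background was 78.0% and the ratio of percentiles 51.1 on DMSO 2, 97.9% and 7.12 on rapamycin 3, 84.2% and 21.9 on PP242 1, and 96.2% and 13.6 on PP242 4. The median correlation of an array with the other 11 was 0.963 to 0.983 for the 8 arrays and 0.616 for rapamycin 3. The arrays lay on 3 slides, each scanned once. Slide 1 held DMSO 1, DMSO 4, rapamycin 1 and PP242 2, slide 2 held DMSO 2, rapamycin 2, PP242 3 and PP242 4, and slide 3 held DMSO 3, rapamycin 3, rapamycin 4 and PP242 1, so each slide held all 3 groups.

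**Figure D1:**
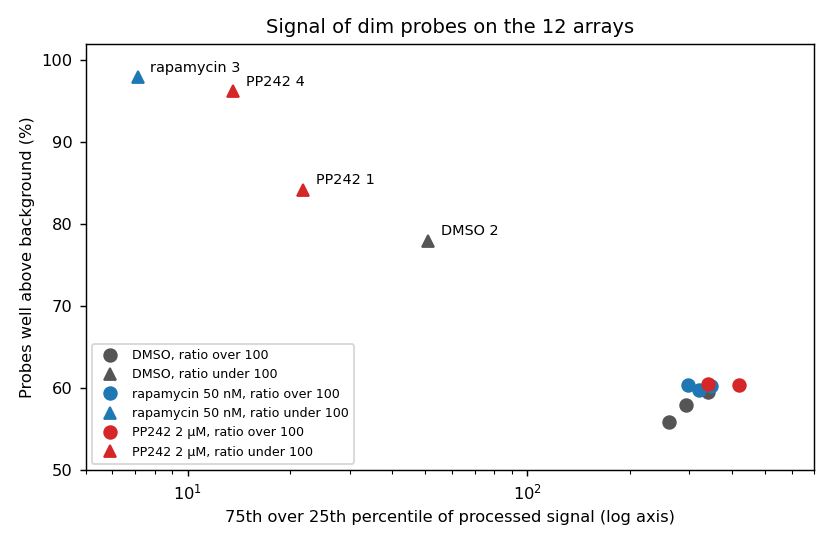
Each point is 1 array, with the ratio of the 75th to the 25th percentile of its processed signal on a log axis and the percentage of probes well above background on the other axis, coloured by group. The 8 arrays with a ratio of 261 or more (circles) lie between 55.8% and 60.5%, and the 4 arrays with a ratio of 51.1 or less (triangles) lie between 78.0% and 97.9%.

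Because of this, each comparison is given for the planned fit of all 12 arrays and for a fit of the 8 arrays with a ratio above 100 (3 DMSO, 3 rapamycin and 2 PP242 arrays), which was chosen after the data had been seen. With the planned scaling of 12 arrays, the median log2 fold change of all genes was 0.24 for rapamycin against DMSO, 0.41 for PP242 against DMSO and 0.23 for PP242 against rapamycin. It was -0.39, -0.46 and -0.01 when each array was centred on its median, -0.06, 0.02 and -0.01 after quantile normalisation, and -0.01, -0.01 and 0.02 in the 8-array fit. The set test used for lists compares each list with all other genes, so its result is relative to this shift. Values below are log2 fold changes with their standard error, from the 8 arrays unless the 12-array fit is named.

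PP242 was first compared with DMSO, which asks what inhibition of the kinase changes. In the planned fit of 12 arrays, S100g, which encodes a calcium-binding protein, was higher with PP242 by 3.16 ± 0.46 on the log2 scale (8.93-fold, n = 4 and 4, limma adjusted p = 0.0246) and Ypel1 by 2.88 ± 0.27 (7.35-fold, limma adjusted p = 0.0115). Inca1, Tcp11l2, Zfp467, N4bp2l1, Arhgef4 and Hdac11, a histone deacetylase, rose by 2.35 to 2.88. Tfrc, the transferrin receptor that takes up iron, fell by 3.19 ± 0.47 (9.12-fold, limma adjusted p = 0.0246). Trib3, a pseudokinase induced by ATF4, fell by 2.57 ± 0.35 (limma adjusted p = 0.0226), and Ak4, a mitochondrial adenylate kinase, fell by 2.06 ± 0.30 (limma adjusted p = 0.0246). Mfsd2a, Fancb and Ddias were the other named genes that fell, with log2 changes of -1.98, -1.54 and -1.48. In all, 88 of 25581 genes passed in this fit, 77 higher and 11 lower, and 2214 had an unadjusted p under 0.05, where 1279 are expected by chance.

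On the 8 arrays, S100g rose by 3.37 ± 0.22 (10.3-fold, n = 2 and 3, limma adjusted p = 0.000422), Ypel1 by 3.07 ± 0.18 (limma adjusted p = 0.000391) and Txnip, an inhibitor of thioredoxin and of glucose uptake, by 2.89 ± 0.23 (7.41-fold, limma adjusted p = 0.00063). Cnbd2, Inca1, Tcp11l2, Arhgef4 and Paqr7 rose by 2.83 to 3.07. Cth, which makes cysteine from cystathionine, fell by 4.00 ± 0.40 (15.9-fold, limma adjusted p = 0.00124). Mthfd2, a mitochondrial folate enzyme, fell by 3.00 ± 0.26 (8.03-fold), Tfrc by 3.10 ± 0.51 (8.59-fold) and the immediate early gene Egr1 by 2.77 ± 0.33 (6.82-fold). Car6, Cytip, Cox6a2 and Ranbp3l fell by 3.73, 2.94, 2.90 and 2.75. Here 5138 of 19591 genes passed, 2524 higher and 2614 lower, of which 1849 changed by at least 2-fold, and 59.0% of genes had groups that did not overlap, where chance gives 20%. All 88 genes of the 12-array fit were among them with the same sign. With array weights, a planned setting, 9140 genes passed, 4813 higher and 4327 lower, and 5074 of the 5138 were called with the same sign. The weights were 0.0201 for rapamycin 3, 0.0918 for PP242 4, 0.216 for PP242 1, 0.342 for DMSO 2, 0.632 for rapamycin 4 and 0.715 for DMSO 4, against 2.98 to 7.16 for the other 6 arrays. This setting therefore nearly drops the 4 raised arrays, and the agreement is not support from all 12.

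The number of calls depended on single arrays. In the 12-array fit it was 0 without any of DMSO 1 to 4 or PP242 1 to 3, 2 without rapamycin 1 or 2, and 3134 without rapamycin 3. On the 8 arrays it was 1805 without PP242 3 and 1985 without PP242 2, and no called gene changed sign when any array was left out. In these 2 fits PP242 has 1 array, which is assumed to vary like the DMSO and rapamycin arrays, so they hold no replicate of PP242. Of 152 named genes called on the 8 arrays, 88 were called in all 8 of these fits, and Cytip, Ranbp3l and Paqr7 were called in 1, 2 and 4 of them. With slide as a block, 0 genes passed on 12 arrays by limma. On 8 arrays 1426 passed with that block, 685 higher and 741 lower, and S100g, Ypel1, Txnip and Cth had log2 changes of 3.27, 2.99, 2.96 and -4.02, with limma adjusted p of 0.018 for S100g and 0.0298 for Cth. Tfrc did not pass with the block (-3.31, limma adjusted p = 0.0592). Within each of the 3 slides all 88 genes had the sign of the 12-array fit, no independent evidence, as they were selected on these arrays. Slides 2 and 3 hold raised arrays in every comparison, so here and below they do not decide a sign. The split of calls into higher and lower moved with the scaling: 26 rose and 19 fell after quantile normalisation of 12 arrays, 67 rose and 48 fell with the deposited log2 table, and 0 passed with median centring.

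Genes not well above background on any array of 1 group have only a bound. With PP242, Fmo5 was at least 6.90-fold higher (limma adjusted p = 0.00471), Hsd17b1 at least 3.65-fold and Bdh1 at least 3.52-fold. Slc17a6 was at least 6.45-fold lower (limma adjusted p = 0.00428), Sh2d1b1 at least 6.20-fold and Evi2a at least 4.83-fold. On 12 arrays the largest bound was for Trim34a, at least 4.76-fold higher with PP242, and it did not pass (limma adjusted p = 0.213).

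Genes of cell division fell with PP242. All 30 measured members of the mitosis list fell (30 adjusted over the list alone), with a median of -1.84 and a camera adjusted p of 5.31e-24, and adjusted p = 0.203 with an estimated correlation. Among them were the cyclins Ccna2 (-1.90 ± 0.09) and Ccnb1 (-1.94 ± 0.11), the kinase Melk (-1.75 ± 0.08) and Prc1 (-1.90 ± 0.10), which bundles spindle microtubules. Of 29 measured DNA replication genes, 28 fell (29 adjusted over the list alone), with a median of -1.24 (camera adjusted p = 8.76e-19, adjusted p = 0.0939 with an estimated correlation). Thymidine kinase Tk1 fell by 2.31 ± 0.08 (limma adjusted p = 0.000321), Ccne1 by 1.82 ± 0.12, the helicase factor Cdc45 by 1.42 ± 0.09 and the ribonucleotide reductase subunit Rrm1 by 1.23 ± 0.08. On 12 arrays the medians were -1.50 for mitosis and -1.12 for replication, 0 members passed over all genes, and 28 and 17 passed adjusted over the list alone. Within slides 1, 2 and 3 of the 12 arrays the mitosis median was -1.83, -1.03 and -1.78 and the replication median -1.28, -0.69 and -1.30. With slide as a block on 8 arrays the medians were -1.75 and -1.30. Of 12 measured G1 cyclins and CDK inhibitors, Rbl1 (-1.35 ± 0.08) and Ccnd2 (-0.84 ± 0.14) fell, 2 also adjusted over the list alone, and the list was not called on 8 arrays (median -0.20, camera adjusted p = 0.2). It was called lower on 12 (-0.13, camera adjusted p = 0.0149, adjusted p = 0.542 with an estimated correlation), also with slide as a block (-0.09, camera adjusted p = 0.0137). Ccnd1 was not analysed here.

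Genes for amino acid supply fell as well. Of 27 measured ATF4 targets, 17 fell and 1 rose (17 and 2 adjusted over the list alone), with a median of -1.10 (camera adjusted p = 9.78e-07, adjusted p = 0.373 with an estimated correlation). Next to Cth and Mthfd2, the serine synthesis enzyme Psat1 fell by 1.90 ± 0.15 (limma adjusted p = 0.000597) and Shmt2 by 1.54 ± 0.14. Atf3, a stress-induced transcription factor, went against the list and rose by 2.34 ± 0.25 (limma adjusted p = 0.00144). Atf5 did not pass (-0.23 ± 0.20), nor did Slc38a2 (0.12 ± 0.13), whose probes disagreed in sign. Of 20 aminoacyl-tRNA synthetases 13 fell and 1, Qars, rose by 0.30 (14 and 1 adjusted over the list alone), with a median of -0.56 (camera adjusted p = 4.62e-05, adjusted p = 0.436 with an estimated correlation). Mars1 fell by 0.94 ± 0.10, Yars by 0.95 ± 0.11, Cars by 1.34 ± 0.21 and Gars by 1.04 ± 0.16. The call of Qars was kept in 1 of the 8 fits that leave out an array. The 12-array medians were -1.18 and -0.62. Trib3 was the single member of the 2 lists that passed over all genes there, and 1 rose and 12 fell among ATF4 targets adjusted over the list alone, against 1 lower synthetase. Within slides 1, 2 and 3 the ATF4 median was -1.12, -0.90 and -1.21 and the synthetase median -0.62, -0.38 and -0.72, and with slide as a block on 8 arrays they were -1.26 and -0.58.

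Of 29 ribosome biogenesis genes, 18 fell (21 fell and 1 rose adjusted over the list alone), with a median of -0.63 (camera adjusted p = 2.51e-06, adjusted p = 0.443 with an estimated correlation). Nolc1 fell by 1.71 ± 0.18, Nhp2, a component of snoRNA-protein particles, by 1.25 ± 0.11, Rrs1 by 1.06 ± 0.15 and Bysl by 0.70 ± 0.09, while Npm1 (-0.02) and Ncl (-0.20) did not pass. Its median was -0.59 on 12 arrays, -0.65, -0.37 and -0.74 within slides 1, 2 and 3, and -0.52 with slide as a block on 8 arrays. Of 24 translation factors, 8 fell and 2 rose (9 and 3 adjusted over the list alone), and the list was not called on 8 arrays (median -0.19, -0.10 without PP242 3 and -0.30 without PP242 2, camera adjusted p = 0.145) but was on 12 (-0.34, camera adjusted p = 0.000788). Eif5a fell by 1.02 ± 0.09 and the cap-binding protein Eif4e by 0.59 ± 0.09, and the elongation factor Eef2 rose by 0.65 ± 0.11. None of the 27 cytosolic ribosomal proteins passed (0 by limma, also adjusted over the list alone), with Rps2 (-0.12 ± 0.26) as an example. Their median was 0.01 on 8 arrays, where it was -0.14 without PP242 2 and 0.20 without PP242 3 and the list was called in 1 of the 8 fits that leave out an array. It was -0.10 on 12 arrays, where the list was called lower than other genes (camera adjusted p = 0.0393) but not with slide as a block (-0.05, camera adjusted p = 0.079). Of 28 genes of mitochondrial respiration 2 rose and 3 fell (1 and 2 adjusted over the list alone), with cytochrome c, Cycs, at -1.08 ± 0.11 and Sdha at 0.50 ± 0.13, and the list was called on 12 arrays only (medians -0.15 and -0.31 on 8 and 12, and -0.07 on 8 without PP242 3), apart from 1 of the 8 fits that leave out an array.

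Glucose metabolism, hypoxia and redox lists were lower with PP242. In glycolysis 10 of 19 members fell (10 adjusted over the list alone; median -0.63, camera adjusted p = 0.00551, adjusted p = 0.436 with an estimated correlation), among them the glucose transporter Slc2a1 (-2.10 ± 0.21), Pfkl (-1.51 ± 0.13), Ldha (-1.50 ± 0.12) and Tpi1 (-0.87 ± 0.10), and Aldoa (-0.20 ± 0.17) and Gapdh (-0.31 ± 0.15) did not pass. In the hypoxia list 9 of 19 fell (9 fell and 1 rose adjusted over the list alone; median -0.76, camera adjusted p = 0.00551, adjusted p = 0.203 with an estimated correlation). Ddit4, an inhibitor of mTORC1 signalling, fell by 2.04 ± 0.25, Higd1a by 1.86 ± 0.11, Bnip3 by 1.22 ± 0.13 and the kinase Pdk1 by 0.82 ± 0.12, while Hif1a (-0.13 ± 0.15) and Vegfa (-0.58 ± 0.25) did not pass. Without DMSO 4 the hypoxia median was -0.48, and the call was kept. Of 19 NRF2 targets, 10 fell and 1 rose (10 and 1 adjusted over the list alone; median -0.49, camera adjusted p = 0.00791, adjusted p = 0.436 with an estimated correlation). Nqo1 fell by 1.70 ± 0.27, Gsr by 0.89 ± 0.09 and Txn1 by 0.80 ± 0.12, the cystine transporter Slc7a11 was at least 4.67-fold lower, and Gstm1 rose by 0.52. Of 19 genes of the pentose phosphate pathway and nucleotide synthesis, 8 fell (8 adjusted over the list alone; median -0.34, camera adjusted p = 0.00144, adjusted p = 0.203 with an estimated correlation), with Prps1 at -0.63 ± 0.11 and Pgd at -0.56 ± 0.10. Of 18 ER stress genes, 9 fell (11 fell and 1 rose adjusted over the list alone; median -0.54, camera adjusted p = 0.00251, adjusted p = 0.373 with an estimated correlation), with Sdf2l1 at -1.32 ± 0.13 and Calr at -0.70 ± 0.09, while Hspa5 did not pass (-0.41 ± 0.13). The 12-array medians of these 5 lists, in this order, were -0.65, -0.60, -0.57, -0.38 and -0.50. With slide as a block on 8 arrays they were -0.64, -0.56, -0.53, -0.32 and -0.56. Each of the 5 medians was negative within each slide, at -0.41, -0.67 and -0.75 for glycolysis and -0.68, -0.34 and -0.62 for the hypoxia list.

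Growth factor and ERK-induced genes fell: 12 of 23 members fell and 1 rose (16 and 1 adjusted over the list alone), with a median of -1.08 (camera adjusted p = 0.00014, adjusted p = 0.443 with an estimated correlation). Next to Egr1, the ligands Ereg (-2.70 ± 0.25) and Hbegf (-1.12 ± 0.16) and the transcription factor Egr2 (-2.15 ± 0.27) fell, while Junb (-0.59 ± 0.31) and Dusp1 (1.47 ± 0.88) did not pass. The median was -0.78 on 12 arrays, -1.13, -0.28 and -0.73 within slides 1, 2 and 3, and -1.01 with slide as a block on 8 arrays.

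FoxO targets rose with PP242, 9 of 23 members with none lower (11 and 0 adjusted over the list alone), with a median of 0.55 on 8 arrays and 0.50 on 12 that was -0.39 with median centring of 12 arrays (camera adjusted p = 0.000154 on 8 arrays, adjusted p = 0.203 with an estimated correlation). Next to Txnip, the pro-apoptotic genes Bbc3 (1.31 ± 0.12) and Bcl2l11 (1.15 ± 0.17) rose and the ubiquitin ligase Trim63 was at least 1.73-fold higher, while Sod2 did not pass (0.22 ± 0.22). Of 24 autophagy genes, 8 rose and 1 fell (9 and 2 adjusted over the list alone), with a median of 0.62 that was 0.29 and not called on 12 arrays and -0.61 with median centring of them (camera adjusted p = 0.00938 on 8 arrays, adjusted p = 0.538 with an estimated correlation). The kinase Ulk2 rose by 0.76 ± 0.09, the cargo receptor Nbr1 by 0.87 ± 0.12 and Atg13 by 0.67 ± 0.11, and Wipi2 fell by 0.45 ± 0.10, with probes that disagreed in sign. Of 27 interferon response genes, 5 rose (5 adjusted over the list alone), among them Xaf1 (1.70 ± 0.23), Ifi35 (0.90 ± 0.11), Irf9 (0.89 ± 0.12) and Stat2 (0.85 ± 0.11). That list had a median of 0.53 and was not called on 8 arrays (camera adjusted p = 0.0552). It was called on 12 arrays (median 0.69, camera adjusted p = 0.00673, adjusted p = 0.386 with an estimated correlation), where median centring gave -0.20, and with slide as a block on 8 arrays (0.65, camera adjusted p = 0.027). Its 8-array median was 0.25 without DMSO 3 and 0.73 without DMSO 4, and it was called in 4 of the 8 fits that leave out an array. Of 30 lysosome genes Tfeb alone rose, by 0.52 ± 0.14 (0 adjusted over the list alone), and the list was not called (median 0.53, 0.19 without DMSO 4, camera adjusted p = 0.17). Within slides 1, 2 and 3 the FoxO median was 0.55, 0.57 and 0.31, the autophagy median 0.61, 0.19 and 0.14 and the interferon median 0.34, 0.80 and 1.09, and with slide as a block on 8 arrays the FoxO and autophagy medians were 0.53 and 0.48. The PP242 arrays of the 8-array fit include none numbered 4. DMSO 4 and rapamycin 4 differed from the other arrays of their groups by a median of 1.07 in the interferon list, 0.56 in the ERK list and -0.51 in the sterol synthesis list, and the lysosome list was lower on them too.

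Sterol synthesis genes did not shift as a group in a stable direction. Their median with PP242 was -0.30 on 12 arrays (camera adjusted p = 0.000804, adjusted p = 0.649 with an estimated correlation) and 0.04 on 8 arrays (camera adjusted p = 0.767). It was -0.16 after quantile normalisation of 12 arrays, 0.18, -0.63 and -0.25 within slides 1, 2 and 3, and -0.27 and -0.04 with slide as a block on 12 and 8 arrays, and lay between -0.02 and 0.14 when each of the 8 arrays was left out. Of 19 members, 1 rose on the 8 arrays, Mvd by 0.47 ± 0.10, and 0 adjusted over the list alone. Msmo1 (0.04 ± 0.29) did not pass. In the sterol uptake list Tmem97 (-2.13 ± 0.11), Lrp8 (-1.22 ± 0.18) and Stard4 (-0.71 ± 0.11) fell, 3 of 13 members (4 adjusted over the list alone), and the median of 0.27 had the opposite sign to the mean of -0.08 and to the test, which did not call the list on 8 arrays (camera adjusted p = 0.767). Without PP242 3 that median was 0.12. On 12 arrays the list was called lower than other genes (median 0.01, camera adjusted p = 0.0149, adjusted p = 0.542 with an estimated correlation), also with slide as a block (0.03, camera adjusted p = 0.0174). Insig1 (0.61 ± 0.40), Srebf1 (0.11 ± 0.10), Srebf2 (0.23 ± 0.14) and Fasn (-0.09 ± 0.19) did not pass. In fatty acid synthesis 1 of 19 rose (1 adjusted over the list alone), Acacb by 2.64 ± 0.18, with its 2 probes at 0.38 and 2.64. The median of -0.08 and mean of 0.12 of the list differed in sign, and the list was not called on 8 arrays (camera adjusted p = 0.885). On 12 arrays it was called lower (-0.18, camera adjusted p = 0.0335), but not with slide as a block (camera adjusted p = 0.079). Of 9 LXR targets Mylip and Nr1h2 rose, by 0.36 and 0.34, and Apoe fell by 0.96 ± 0.16, with 2 and 1 adjusted over the list alone (median 0.31, camera adjusted p = 0.608).

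Of 26 components of the mTOR and insulin pathway, 4 rose and 5 fell (6 and 5 adjusted over the list alone). The median of 0.05 and the mean of -0.03 differed in sign, and the list was not called (camera adjusted p = 0.885). Pdpk1 rose by 0.54 ± 0.08 and Tsc2 by 0.73 ± 0.12, and Akt1 fell by 0.56 ± 0.09. Mtor was higher by 0.35 ± 0.10 (limma adjusted p = 0.0472), and this call was kept in 1 of the 8 fits that leave out an array. Rictor (0.36 ± 0.11, limma adjusted p = 0.0512) and Rptor (-0.33 ± 0.15) did not pass. Irs2 was not analysed here. Of 18 p53 targets 3 rose and 3 fell (3 and 3 adjusted over the list alone; median -0.26, -0.40 without DMSO 4 and -0.17 without DMSO 1, camera adjusted p = 0.635), with the death receptor Fas at 1.06 ± 0.16 and Gtse1 at -2.03 ± 0.23. The p53 list was called lower on 12 arrays (-0.29, camera adjusted p = 0.00834, adjusted p = 0.649 with an estimated correlation), also with slide as a block (-0.29, camera adjusted p = 0.0118). Of 20 inflammatory genes 2 rose and 2 fell (2 and 2 adjusted over the list alone; median 0.07, with a test of the opposite sign, camera adjusted p = 0.974), with the chemokine Cxcl5 at -2.27 ± 0.20 and Nfkbia at 0.98 ± 0.10. Of 17 matrix proteases and inhibitors 4 rose and 2 fell (4 and 2 adjusted over the list alone; median 0.62, 0.03 without DMSO 4, camera adjusted p = 0.381), with Adamts1 at 1.61 ± 0.17 and Plaur at -0.55 ± 0.14. Of 27 matrix genes Thbs2 rose by 1.07 ± 0.15, and Col4a1 and Serpinh1 fell by 0.86 and 0.40, 1 and 1 adjusted over the list alone, and the list was not called (median 0.15, 0.07 without DMSO 1 and 0.28 without DMSO 4, camera adjusted p = 0.443).

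Markers of other cell types moved with the arrays whose dim probes were raised. On 12 arrays the median with PP242 was 1.97 for 13 epithelial markers (camera adjusted p = 0.0443, adjusted p = 0.797 with an estimated correlation), 1.37 for 10 endothelial, 1.28 for 12 macrophage and 1.22 for 12 adipocyte markers, against 0.41 for all genes, with 0 members called by limma. The epithelial call was lost with slide as a block (1.47, camera adjusted p = 0.079). On 8 arrays, 5 epithelial markers were measured with a median of -0.67, 5 macrophage markers with 0.06, where the test had the opposite sign, 7 adipocyte markers with 0.76 and 4 endothelial markers with 0.55. Without DMSO 4 the epithelial and adipocyte medians were -0.16 and 0.14, and without PP242 2 the epithelial and macrophage medians were -1.19 and -0.13. None of these lists was called there, and the endothelial list had too few members for the test. Lipe (0.70 ± 0.18), Pnpla2 (0.76 ± 0.21), Eng (1.25 ± 0.29) and Aif1 (1.82 ± 0.28) rose, and Cd14 (-0.99 ± 0.08) and Csf1r (-0.37 ± 0.09) fell. Of 12 smooth muscle markers Smtn fell by 1.00 ± 0.24, and Acta2 (0.40 ± 0.95) and Tpm1 (0.57 ± 0.51) did not pass. The median of that list was 0.46 on 8 arrays, -0.05 and 0.68 on them without DMSO 4 and DMSO 3, and -0.03 on 12, and DMSO 4 and rapamycin 4 differed from the other arrays of their groups by a median of -1.30 in it.

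Over the 33 lists, camera with the preset correlation called 22 for PP242 on 12 arrays, 3 higher and 19 lower, and 13 of the 32 lists that could be tested on 8 arrays, 2 higher and 11 lower. All 13 stayed called when any of the 8 arrays was left out, but in 2 of these fits PP242 has 1 array and the spread comes only from the DMSO and rapamycin groups. None of the calls of any comparison held with an estimated correlation, and for PP242 against DMSO the smallest camera adjusted p was then 0.216 on 12 arrays and 0.0939 on 8. Fry, which tests only whether the genes of a list move one way on balance, called 0 lists on 12 arrays and 17 on 8 for this comparison.

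**Figure D2:**
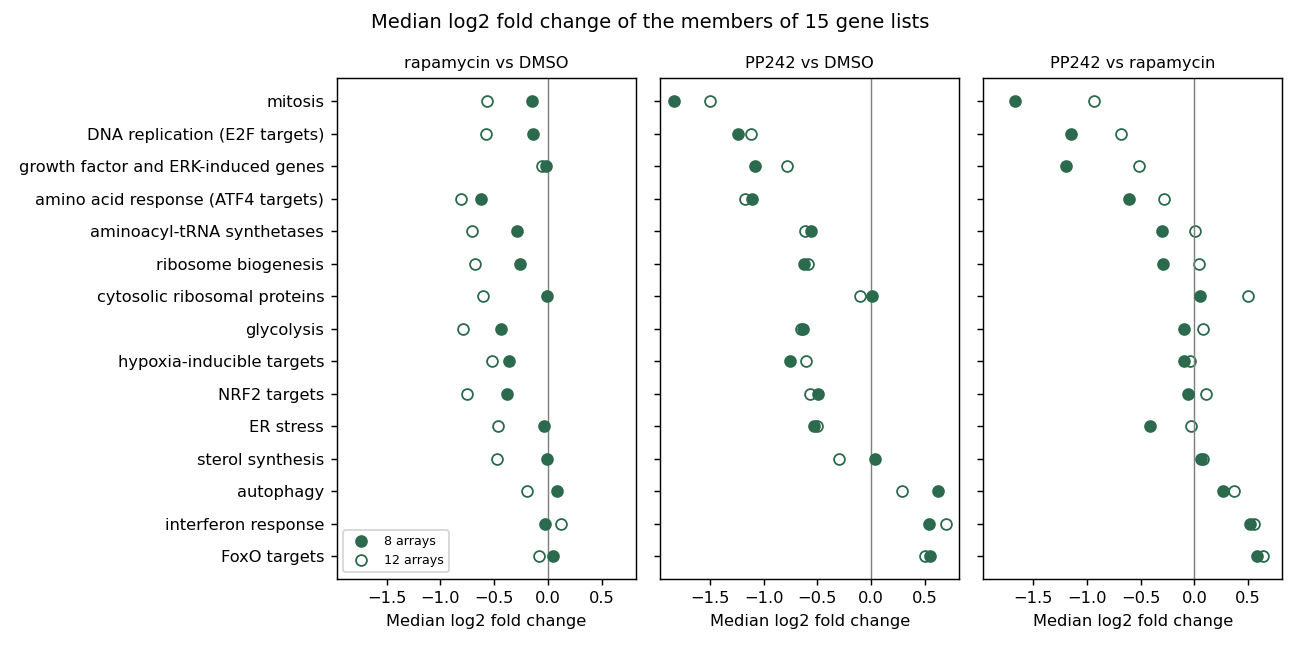
Median log2 fold change of 15 gene lists in the 3 comparisons, with filled points for the 8-array fit and open points for the 12-array fit. With PP242 against DMSO the mitosis list lies at -1.84 and -1.50 and FoxO targets at 0.55 and 0.50, whereas sterol synthesis lies at 0.04 on 8 arrays and -0.30 on 12, and FoxO targets, autophagy and interferon response turn to -0.39, -0.61 and -0.20 with median centring of 12 arrays.

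Rapamycin was compared with DMSO in the same way, to find what its action on mTORC1 changes. In the fit of 8 arrays Anxa8, a member of the annexin family, rose 2.84-fold (SE 0.12 on the log2 scale, n = 3 and 3, limma adjusted p = 0.0391). Fbxl20, a subunit of a ubiquitin ligase, rose by 1.05 ± 0.10 (2.07-fold, limma adjusted p = 0.0481) and Bckdha, a subunit of the enzyme that degrades branched-chain keto acids, by 0.87 ± 0.08 (1.83-fold, limma adjusted p = 0.0481). Ak4 fell by 1.14 ± 0.08 (2.20-fold, limma adjusted p = 0.0205). Ypel1 (1.57 ± 0.16, limma adjusted p = 0.053), Higd1a (-0.73 ± 0.10, limma adjusted p = 0.0755) and Ddit4 (-1.32 ± 0.23, limma adjusted p = 0.117) did not pass. Among genes with only a bound none passed, the largest being Mgll at 2.57-fold higher or more (limma adjusted p = 0.308). In all, 11 of 19591 genes passed, 7 higher and 4 lower, with 2593 at an unadjusted p under 0.05 where 980 are expected. In the planned fit of 12 arrays 0 of 25581 genes passed by limma, with 451 at an unadjusted p under 0.05 where 1279 are expected and a smallest adjusted p of 0.847. Array weights on 12 arrays, which give the 4 raised arrays little weight, called 2509 genes, 1412 higher and 1097 lower, with all 11 among them in the same direction.

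These 11 calls rested on few arrays. Of them 0 were called without DMSO 1, DMSO 3, rapamycin 1, PP242 2 or PP242 3, 1 without rapamycin 2, 7 without DMSO 4 and 11 without rapamycin 4. These fits called 0, 4, 23 and 104 genes in all, and 0 passed with slide as a block by limma. Anxa8, Fbxl20 and Ak4 were called in 2 of the 8 fits that leave out an array and Bckdha in 1, with the same sign in all. With the number 4 as a covariate, which leaves 17 lists called and was added after the data had been seen, 1710 genes passed, 1020 higher and 690 lower.

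No list had a member that passed over all genes with rapamycin in either fit (0 by limma), and lists are described by their members adjusted over the list alone and by their median. ATF4 targets had 17 of 27 members lower adjusted over the list alone on the 8 arrays, with a median of -0.63 (camera adjusted p = 2.7e-12, adjusted p = 0.196 with an estimated correlation). Psat1 (-0.70 ± 0.13), Phgdh (-0.50 ± 0.14) and Cth (-1.37 ± 0.35) are examples that did not pass over all genes. Psat1, Pfkl, Bnip3 and Pdk1 were picked as examples for rapamycin after their values had been seen. Glycolysis had 9 of 19 lower adjusted over the list alone (median -0.43, camera adjusted p = 9.32e-09, adjusted p = 0.194 with an estimated correlation), with Pfkl at -1.10 ± 0.12 and Gapdh at -0.36 ± 0.14. NRF2 targets had 8 of 19 (median -0.38, camera adjusted p = 3.89e-07, adjusted p = 0.194 with an estimated correlation) and hypoxia targets 5 of 19 (median -0.36, camera adjusted p = 2.6e-05, adjusted p = 0.135 with an estimated correlation), with Bnip3 at -1.12 ± 0.11 and Pdk1 at -0.98 ± 0.11. All 29 ribosome biogenesis genes had a negative change, 2 of them passing adjusted over the list alone (median -0.26, camera adjusted p = 2.31e-09, adjusted p = 0.321 with an estimated correlation), with Ncl at -0.26 ± 0.12. Of 20 synthetases 19 had a negative change, with 0 passing adjusted over the list alone by limma (median -0.29, camera adjusted p = 4.1e-07, adjusted p = 0.321 with an estimated correlation). Translation factors (median -0.18, 5 lower and 2 higher adjusted over the list alone), mitosis (-0.15), DNA replication (-0.14), mitochondrial respiration (-0.22, 1 lower), the pentose phosphate and nucleotide list (-0.17, 2 lower) and p53 targets (-0.28) were also called lower, with adjusted p of 0.419, 0.601, 0.317, 0.547, 0.196 and 0.601 with an estimated correlation. Examples are Cdc20 (-0.36 ± 0.12), Pcna (-0.21 ± 0.08) and Phlda3 (-0.32 ± 0.12), none of which passed by limma.

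Matrix genes were called higher on the 8 arrays, with a median of 0.24 that was -0.08 on 12 arrays and -0.72 with median centring of them (camera adjusted p = 0.00225, adjusted p = 0.308 with an estimated correlation), and 25 of 27 members had a positive change. Examples are Col1a2 (0.08 ± 0.14) and Sparc (0.15 ± 0.10), which did not pass. Inflammatory genes were called higher too, with a median of 0.25 on 8 arrays that was -0.03 on 12 (camera adjusted p = 0.0217, adjusted p = 0.196 with an estimated correlation), 3 of 20 passing adjusted over the list alone and Ccl2 at 0.71 ± 0.18. When each of the 8 arrays was left out, the matrix call stayed in 7 of 8 fits, the inflammatory call in 6 and the p53 call in 5, and the other 11 calls stayed in all 8. Without DMSO 4 the medians of synthetases, replication and p53 targets were -0.19, -0.09 and -0.44, without DMSO 1 those of mitochondrial respiration and the matrix were -0.13 and 0.16, and without rapamycin 4 that of mitosis was -0.22. The highest camera adjusted p was 0.0527 for the matrix, without DMSO 1, and 0.209 and 0.0753 for inflammatory genes and p53 targets, both without rapamycin 4. With slide as a block the medians were -0.65 for ATF4 targets, -0.44 for glycolysis, -0.38 for NRF2 targets, -0.35 for hypoxia targets and 0.21 for the matrix. Within slides 1, 2 and 3 the ATF4 median was -0.60, -0.06 and -1.25. Glycolysis was at -0.40, -0.30 and -1.60 and hypoxia targets at -0.46, -0.04 and -1.38. On slide 2 mitosis (0.11), replication (0.22), synthetases (0.15), pentose phosphate (0.13) and ribosome biogenesis (0.03) were positive, with NRF2 targets at -0.00. As above, slides 2 and 3 hold raised arrays and do not decide the sign.

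Sterol synthesis genes had a median of -0.01 with rapamycin on the 8 arrays, where the mean of -0.02 and the test differed in sign (camera adjusted p = 0.949), and -0.47 on 12 arrays (camera adjusted p = 0.000237, adjusted p = 0.568 with an estimated correlation). Without rapamycin 3 the 12-array median was 0.02, and within slides 1, 2 and 3 it was 0.23, 0.41 and -1.36. Insig1 (0.48 ± 0.36), Srebf1 (-0.03 ± 0.09), Srebf2 (0.17 ± 0.12), Fasn (-0.14 ± 0.17), Vegfa (-0.05 ± 0.22), Mtor (0.04 ± 0.09), Rictor (0.29 ± 0.10) and Rptor (-0.15 ± 0.14) did not pass. Ribosomal proteins had a median of -0.01 on the 8 arrays, with a test of the opposite sign (camera adjusted p = 0.949), and of -0.61 on 12 (camera adjusted p = 1.57e-08, adjusted p = 0.526 with an estimated correlation). The remaining lists were not called on the 8 arrays, and many of their medians turned on DMSO 4 or rapamycin 4. The sterol synthesis median was -0.18 without DMSO 4 and 0.21 without rapamycin 4, and the list was called in 1 of the 8 fits that leave out an array. The lysosome median of 0.02 was -0.20 without DMSO 4 and 0.33 without rapamycin 4, with a call in 2 of these fits. Autophagy (median 0.09, with 4 higher adjusted over the list alone) lay between -0.01 and 0.22 with a call in 2, and FoxO targets (0.04) between -0.02 and 0.17 with a call in 1. Fatty acid synthesis (-0.14, called lower with slide as a block at -0.18, camera adjusted p = 0.0306) lay between -0.24 and 0.02 with a call in 3. Matrix proteases (0.10) lay between 0.03 and 0.35 and smooth muscle markers (0.40) between 0.02 and 0.78, each with a call in 2. The interferon median of -0.03 was -0.35 without rapamycin 4 and 0.28 without DMSO 4, and that of ERK-induced genes, -0.02, was -0.28 and 0.16, both with a test of the opposite sign on the 8 arrays. LXR targets (0.04, mean -0.22) lay between -0.22 and 0.14, sterol uptake (0.05, mean -0.05) between -0.09 and 0.14, G1 regulators (0.03) between 0.02 and 0.10, mTOR components (0.04, mean -0.01) between 0.02 and 0.09 and ER stress (-0.04) between -0.08 and 0.00. Adipocyte (-0.03, mean 0.07), macrophage (-0.33, mean 0.04) and epithelial markers (-0.37) lay between -0.26 and 0.06, -0.33 and -0.21, and -0.56 and -0.28, and endothelial markers (0.27) were not tested. On 12 arrays sterol uptake (-0.28, camera adjusted p = 0.0113), fatty acid synthesis (-0.49, camera adjusted p = 0.000618), the lysosome (-0.41, camera adjusted p = 0.000313), mTOR components (-0.30, camera adjusted p = 0.00354), ER stress (-0.47, camera adjusted p = 0.000192) and G1 regulators (-0.16, camera adjusted p = 0.0253) were called lower. Of these only the G1 call was lost with slide as a block on 12 arrays (camera adjusted p = 0.0576). In all, camera called 14 lists on 8 arrays, 2 higher and 12 lower, and 22 on 12 arrays, 2 higher and 20 lower. The 2 higher ones on 12 arrays were epithelial (median 1.08) and endothelial markers (0.85), and both calls were lost with slide as a block (0.56 and 0.45, camera adjusted p = 0.143 and 0.153). Leaving out rapamycin 3 from the 12 arrays left 13 lists called, 9 of them lower.

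PP242 was then compared with rapamycin directly, which asks what the kinase inhibitor changes beyond rapamycin at these doses. On the 8 arrays Atf3 was higher with PP242 than with rapamycin by 3.19 ± 0.25 (9.10-fold, n = 2 and 3, limma adjusted p = 0.00114). S100g (2.27 ± 0.22), Acacb (2.22 ± 0.18), Cnbd2, Stmn4, Dyrk4, Spag6 and the histone gene H2bc4 were higher by 2.15 to 2.67. Egr1 was lower by a log2 change of -2.77 ± 0.33 (6.83-fold, limma adjusted p = 0.00419), and Egr2 (-2.48 ± 0.27), Cth (-2.63 ± 0.40), Mthfd2 (-2.33 ± 0.26) and Slfn9 (-2.34 ± 0.28) were lower too. Ctsw (-2.69 ± 0.46) was lower as well, and Tnnt2 and Mgp, which were called in 1 and 4 of the 8 fits that leave out an array, had changes of -2.83 and -2.70. Zfr2 was at least 3.63-fold higher (limma adjusted p = 0.0298) and Kctd12b at least 4.35-fold lower (limma adjusted p = 0.0399). Ppp1r42, Tprg and Sh2d1b1 had bounds of 3.57-fold or more and did not pass.

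In all, 2761 of 19591 genes differed between the inhibitors, 1319 higher and 1442 lower with PP242, and 53.6% of genes had groups that did not overlap, where chance gives 20%. In the planned fit of 12 arrays 0 of 25581 genes passed by limma, with 890 at an unadjusted p under 0.05 where 1279 are expected. Leaving out rapamycin 3 from the 12 arrays gave 1040 genes. Array weights on 12 arrays, which again rest little on the 4 raised arrays, called 7212, with 2725 of the 2761 among them in the same direction. On the 8 arrays 501 passed without PP242 3, 534 without PP242 2, 1457 without rapamycin 1 and 1481 without rapamycin 2, and 517 with slide as a block. Of 119 named values called on the 8 arrays, 37 were called in all 8 fits that leave out an array and 75 in at least 6, and no called gene changed sign. As above, 2 of these fits hold 1 PP242 array.

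All 30 mitosis genes were lower with PP242 than with rapamycin (30 adjusted over the list alone; median -1.66, camera adjusted p = 1.07e-30, adjusted p = 0.222 with an estimated correlation), with Melk at -1.78 ± 0.08 and Ccna2 at -1.64 ± 0.09. Of 29 replication genes 27 were lower (28 adjusted over the list alone; median -1.15, camera adjusted p = 4.92e-23, adjusted p = 0.0592 with an estimated correlation), with Tk1 at -2.05 ± 0.08, while E2f1 (-0.52 ± 0.16) did not pass. Of 23 ERK-induced genes 8 were lower (13 lower and 1 higher adjusted over the list alone; median -1.20, camera adjusted p = 3.6e-06, adjusted p = 0.536 with an estimated correlation), with Ereg at -2.31 ± 0.25. Of 23 FoxO targets 6 were higher (9 adjusted over the list alone), with a median of 0.58 on 8 arrays and 0.64 on 12 (camera adjusted p = 3.94e-05 on 8 arrays, adjusted p = 0.241 with an estimated correlation), with Txnip at 1.91 ± 0.23 and Bbc3 at 1.23 ± 0.12. ATF4 targets had 10 members lower and 2 higher (14 and 2 adjusted over the list alone; median -0.60, camera adjusted p = 0.000598, adjusted p = 0.632 with an estimated correlation), with Psat1 at -1.20 ± 0.15 and Atf3 again against the list. On 12 arrays the medians of mitosis, replication, ERK-induced and ATF4 genes were -0.94, -0.68, -0.52 and -0.28, with camera adjusted p of 2.22e-32, 1.22e-19, 1.09e-09 and 7.14e-05, and with slide as a block on 8 arrays they were -1.62, -1.17, -1.13 and -0.64. Within slides 1, 2 and 3 the mitosis median was -1.61, -1.13 and -0.67, that of FoxO targets 0.44, 0.24 and 0.86 and that of ATF4 targets -0.61, -0.94 and 0.08, the last on the slide with rapamycin 3.

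ER stress genes were lower with PP242 than with rapamycin, 7 of 18 (9 adjusted over the list alone; median -0.41, camera adjusted p = 0.00128, adjusted p = 0.456 with an estimated correlation), with Manf at -0.77 ± 0.08 and Sdf2l1 at -1.10 ± 0.13. Their median was -0.03 on 12 arrays and 0.56 within slide 3. Ribosome biogenesis had 6 lower and 1 higher, Nop14, whose probes disagreed in sign (8 and 1 adjusted over the list alone), with a median of -0.29 that was 0.04 on 12 arrays (camera adjusted p = 0.00376 on 8 arrays, adjusted p = 0.752 with an estimated correlation). Synthetases had 4 lower (6 lower and 1 higher adjusted over the list alone), with a median of -0.30 that was 0.01 on 12 arrays (camera adjusted p = 0.00733 on 8 arrays, adjusted p = 0.752 with an estimated correlation). In the pentose phosphate and nucleotide list Umps (-0.80 ± 0.13) and Prps1 (-0.54 ± 0.11) were lower, 2 of 19 (2 adjusted over the list alone), with a median of -0.15 that was 0.14 on 12 arrays (camera adjusted p = 0.036 on 8 arrays, adjusted p = 0.482 with an estimated correlation). Interferon response genes were higher, 5 of 27 (6 adjusted over the list alone; median 0.51, camera adjusted p = 0.036, adjusted p = 0.698 with an estimated correlation), with Xaf1 at 1.35 ± 0.23 and Tap1 at 1.00 ± 0.17. Autophagy genes Ulk2 (0.43 ± 0.09) and Atg14 (0.92 ± 0.22) were higher, 2 of 24 (0 adjusted over the list alone by limma), with a median of 0.26 that was -0.23 within slide 2 (camera adjusted p = 0.0321, adjusted p = 0.752 with an estimated correlation). Slide as a block lost this call (0.17, camera adjusted p = 0.0631). On 12 arrays ER stress, ribosome biogenesis, synthetases and the pentose phosphate list were not called (camera adjusted p = 0.496, 0.242, 0.257 and 0.754). A slide block there gave medians of -0.12, -0.03, -0.08 and 0.06 (camera adjusted p = 0.116, 0.0277, 0.0209 and 0.22), with the middle 2 called. When each of the 8 arrays was left out, the autophagy call stayed in 6 of 8 fits, the interferon call in 5 and the pentose phosphate call in 6. The highest camera adjusted p was 0.178 for autophagy, without rapamycin 4 (median 0.09), 0.0953 for interferon response, without rapamycin 2, and 0.142 for the pentose phosphate list, without PP242 2. Camera called 11 lists on 8 arrays (3 higher, 8 lower) and 9 on 12 (5 higher, 4 lower).

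Glycolysis as a list did not differ between the inhibitors by the test (median -0.09, camera adjusted p = 0.572), though Ldha (-0.95 ± 0.12), Slc2a1 (-1.29 ± 0.21) and Pgam1 (-0.57 ± 0.13), 3 of its 19 members, were lower with PP242. Hypoxia targets (-0.10, camera adjusted p = 0.318), with Higd1a lower at -1.13 ± 0.11 and Bnip3 (-0.10 ± 0.13) and Ddit4 (-0.72 ± 0.25) not passing, NRF2 targets (-0.06, camera adjusted p = 0.568) and ribosomal proteins (0.05, camera adjusted p = 0.572) were not called on 8 arrays either. Without PP242 2 and PP242 3 the median of ribosomal proteins was -0.14 and 0.22, with a call in 1 of the 8 fits that leave out an array, and that of glycolysis -0.22 and 0.09. Ribosomal proteins were called higher on 12 arrays (0.50, camera adjusted p = 0.000831), but not with slide as a block (0.39, camera adjusted p = 0.054). Sterol synthesis had a median of 0.06 on 8 arrays (camera adjusted p = 0.723) and 0.08 on 12, where the test had the opposite sign (camera adjusted p = 0.754), and of -0.12, -0.81 and 1.08 within slides 1, 2 and 3. It was -0.18 on 8 arrays without rapamycin 4 and 0.20 without rapamycin 2. None of its members differed (0 by limma, also adjusted over the list alone). In the sterol uptake list Tmem97 (-1.48 ± 0.11), Lrp8 (-1.01 ± 0.18) and Stard4 (-0.50 ± 0.11) were lower with PP242, 3 of 13 (3 adjusted over the list alone). The median of 0.13 and the mean of -0.03 of that list differed in sign, and the median was -0.02 without rapamycin 4. Mtor (0.31 ± 0.10), Rictor (0.07 ± 0.11), Rptor (-0.18 ± 0.15), Insig1 (0.13 ± 0.40), Srebf1 (0.14 ± 0.10), Srebf2 (0.05 ± 0.14), Fasn (0.05 ± 0.19) and Vegfa (-0.53 ± 0.25) did not pass. Sgk1, a kinase downstream of mTORC2, was lower by a log2 change of -0.70 ± 0.11 (limma adjusted p = 0.0117).

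The other lists were not called between the inhibitors on the 8 arrays either. Among G1 regulators Rbl1 was lower with PP242 (-1.48 ± 0.08, 1 of 12, median -0.15, called in 1 of the 8 fits that leave out an array), and among translation factors Eif5a was (-0.70 ± 0.09, 1 of 24, median -0.01). Mitochondrial respiration had 1 member higher and 2 lower (median 0.07), with Cycs at -0.73 ± 0.11. Of p53 targets 3 were higher and 1 lower (median 0.14, 0.01 without rapamycin 4), with Fas at 0.96 ± 0.16 and Gtse1 at -1.44 ± 0.23. NRF2 targets had 2 higher, Gstm1 and Osgin1, and 4 lower, among them Nqo1 (-1.31 ± 0.27). In the matrix list Thbs2 was higher (0.69 ± 0.15) and Col4a1 lower (-0.87 ± 0.16), and its median of -0.01 and mean of 0.03 differed in sign. Matrix proteases had 2 higher and 2 lower (3 and 4 adjusted over the list alone, median 0.60, -0.01 without rapamycin 4), with Adamts1 at 1.47 ± 0.17. Inflammatory genes had 2 higher and 4 lower (2 and 5 adjusted over the list alone, mean -0.15), with Cxcl5 at -2.18 ± 0.20. Tfeb was the 1 lysosome gene that was higher (0.58 ± 0.14, 0 adjusted over the list alone by limma, median 0.39, 0.04 without rapamycin 4, called in 2 of the 8 fits that leave out an array and on 12 arrays, where slide as a block lost the call, with camera adjusted p of 0.0209 and 0.202), Acacb the 1 gene of fatty acid synthesis (median 0.05, -0.06 without rapamycin 4), and Apoe the 1 LXR target that was lower (-0.68 ± 0.16, median 0.19). mTOR components had 2 higher and 1 lower (median 0.05, mean -0.02), adipocyte markers 2 higher (median 0.73), macrophage and smooth muscle markers 1 lower each (medians 0.40, which was -0.02 without rapamycin 4, and 0.06, which was -0.44 without it), and epithelial and endothelial markers 0 by limma (medians 0.22, which was -0.80 without PP242 2, and 0.31).

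**Figure D3:**
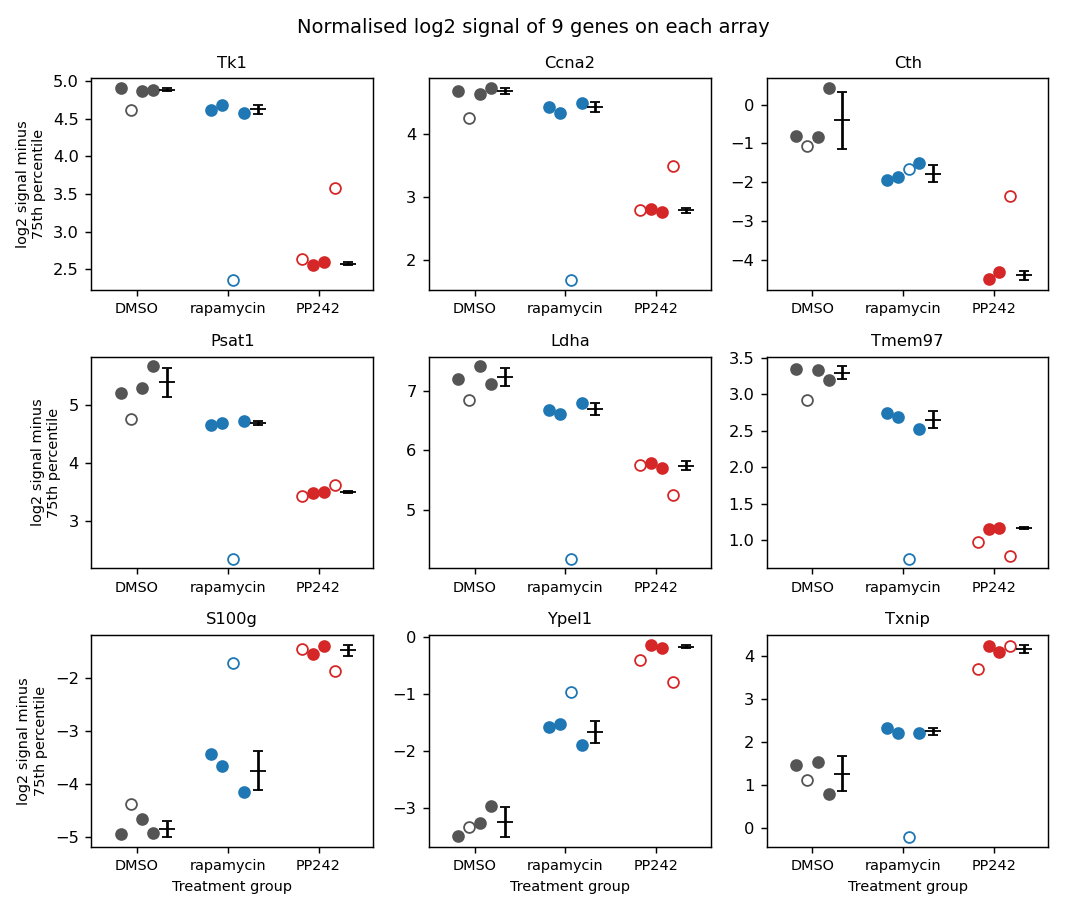
Normalised log2 signal of 9 genes on each array, by group, with filled points for the 8 arrays, open points for the 4 arrays with raised dim probes and bars for the mean and SD of the filled points (n = 3, 3 and 2). With PP242 against DMSO, Tk1, Ccna2, Cth, Psat1, Ldha and Tmem97 fell 4.95-fold, 3.73-fold, 15.9-fold, 3.74-fold, 2.82-fold and 4.37-fold, and S100g, Ypel1 and Txnip rose 10.3-fold, 8.38-fold and 7.41-fold.

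The responses to both inhibitors were then set against each other. Fbxl20 and Bckdha rose with both, by 1.05 and 0.87 with rapamycin and by 1.98 and 1.64 with PP242. Anxa8 also rose with both, 2.84-fold with rapamycin and by a log2 change of 0.66 with PP242, and Ak4 fell with both, by 1.14 and 2.26. For these 4 genes PP242 and rapamycin also differed (0.93 ± 0.11, 0.77 ± 0.09, -0.85 ± 0.14 and -1.12 ± 0.09, each passing by limma). On the 8 arrays 6 genes rose and 3 fell with both inhibitors, where independent lists give 0.902 and 0.534, and both comparisons use the same DMSO arrays. A total of 1242 genes rose and 1341 fell with PP242 and differed in the same direction from rapamycin, where independent lists sharing no arrays give 170 and 192, and 1 gene did so in opposite directions. Among those were Cnbd2, Ypel1, Inca1 and Tcp11l2, with rapamycin values of 0.41, 1.57, 1.06 and 1.33, and Cth, Mthfd2, Egr1 and Ereg, with rapamycin values of -1.37, -0.68, 0.00 and -0.38, none of which passed with rapamycin by limma. On 12 arrays 0 genes were called in both comparisons of either pair by limma, where 451, 2214 and 890 genes had an unadjusted p under 0.05 in the 3 comparisons.

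Across all genes, which are not independent replicates, the changes with both inhibitors correlated with a Pearson r of 0.51 and a Spearman rho of 0.60 on 8 arrays. In 100 simulations of unchanged groups that share the DMSO arrays r was also 0.51, while the covariance was 0.164 against 0.0972 simulated, a difference of 0.0665. On 12 arrays r was 0.83 (rho 0.84) against a simulated 0.17, with a covariance of 0.758 against 0.182, and 0.50 to 0.63 in 6 ways of giving each inhibitor its own DMSO arrays. It was 0.06 without rapamycin 3 and 0.51 without PP242 4.

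**Figure D4:**
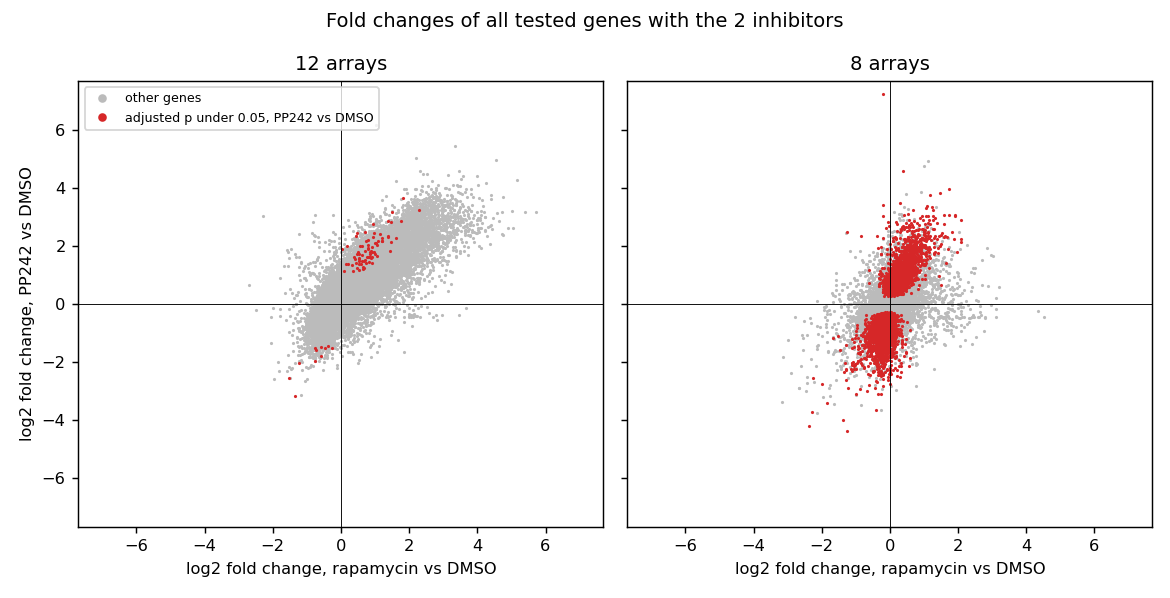
Log2 fold change with rapamycin against that with PP242, 1 point per gene, on 12 and on 8 arrays. Genes that passed for PP242 against DMSO are red (88 and 5138). Here r is 0.83 and 0.51, against 0.17 and 0.51 in simulations that share only the DMSO arrays and lack other shared deviations.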

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

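Tests on the raised arrays against scanner background and treatment, on rapamycin 3 and on shared slides were chosen only after the result was seen. Each array was compared with the other arrays of its group for 12 measures, and 11 values stood far from the rest. Chance alone marks about 1 in 20 groups. The lists among these measures were picked after the list results had been seen.

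On rapamycin 3 the ratio of the 75th to the 25th percentile was 7.12, 97.9% of probes were well above background, the negative control signal was 170 and the slope of the spike-in controls was 0.798. Its mean normalised log2 level was 0.96 for the mitosis list and 1.20 for the DNA replication list. DMSO 2 had 78.0% of probes well above background and 3298 outlier spots. The negative control signal was 61 on PP242 1. On PP242 4 the mean level was 2.17 for the mitosis list and 2.32 for the DNA replication list.

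For the raised dim probes of DMSO 2, rapamycin 3, PP242 1 and PP242 4, scanner background, genomic DNA copied along with the RNA, and the treatments were weighed. Dim probes were raised 4.77-fold, 273-fold, 15.1-fold and 33.5-fold and negative controls 0.931-fold, 5.86-fold, 2.10-fold and 1.03-fold, so for 2 of the 4 arrays scanner background is an unlikely explanation. As 1 of the 4 is a DMSO array, treatment alone does not account for it. Chromosome means of dim probes correlated between the 4 arrays with a median of 0.881, against 0.562 between the other 8, which is consistent with genomic DNA as a hypothesis that no measurement here tests directly.

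With rapamycin 20 lists were called lower on 12 arrays, and 9 without rapamycin 3. On the 8 arrays 12 were called lower, all 12 of them also among the 20. The calls of sterol synthesis, ribosomal proteins and the lysosome, which were made on 12 arrays only, may therefore rest on that array, with 9 lists left without it.

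DMSO 4 and rapamycin 4 shared a deviation from the other arrays of their groups. They shared 0 slides, so a common slide or scan does not account for it. After the mean profile of the other 3 raised arrays had been regressed out, the deviation of PP242 4 correlated with the shared one at 0.749, and those of DMSO 2, rapamycin 3 and PP242 1 at -0.637, -0.277 and 0.03. The deviations of DMSO 2 and rapamycin 3 were taken from group means that include DMSO 4 or rapamycin 4. This lowers their correlations and can raise that of PP242 4, so the contrast between these arrays decides nothing. With only PP242 1 regressed out, the correlation of PP242 4 was 0.616, and without regression PP242 4 correlated at 0.33 with DMSO 4 and -0.20 with rapamycin 4. Whether the arrays numbered 4 share an experiment, which the labels do not state, stays open.

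With 4 arrays against 4, there are 35 ways to split them. For PP242 the real split gave 88 genes and the highest other 0, so 1 of 35 splits, the real one, reached the real value. This fit has no block. That share is the smallest that 35 splits can give, and other comparisons were tested in the same way. Chance is therefore made less likely for this fit but is not excluded. With slide as a block the same comparison gave 0 genes, and these splits do not keep to slides. For rapamycin the real split gave 0 genes and the highest other 0. A count of 0 is reached by 35 of 35 splits whatever the data, so this decides nothing about chance. Between the inhibitors the real split gave 0 genes and the highest other 6642, a split that puts PP242 1, PP242 4, rapamycin 3 and rapamycin 4 together and so points to a structure of the samples. Its real count of 0 is also reached by 35 of 35 splits whatever the data and decides nothing about chance. For rapamycin on 8 arrays there are 10 splits, too few to exclude chance.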

How the results depend on the processing

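Of 224 named values called on the 8 arrays and compared across settings, 224 had the same sign on the planned 12 arrays and 15 were also called there. With median centring of 12 arrays 203 had the same sign, and without rapamycin 1, 2 or 4 of the 12 arrays 218. Counts of calls and the sterol synthesis list depended on the settings, and the cause was not tested except where fewer arrays or genes are named. All settings on 8 arrays, the ratio of percentiles as a covariate and the numbered covariate were chosen after the data had been seen. Normexp on the mean signal was not run, as that column is absent. On the 4 raised arrays signal over background limits dim genes.

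For PP242 against DMSO, 88 genes on 12 arrays became 45 with quantile normalisation, 0 with median centring, 163 with the median signal quantile normalised, 2 with no filter, 322 with probes detected on all arrays, 1717 with only the 2 groups compared, 0 with slide as a block, 201 with an intensity trend, 9140 with array weights, 34 with normexp on the median signal and 1249 with the ratio covariate. On 8 arrays the count was 5138, and 4306 with the 12-array filter, 1426 with slide as a block, 8597 with the number 4 covariate, 8975 with array weights, 4639 with the median signal, 4127 with median centring, 4510 with the deposited log2 table and 5579 with a trend.

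In the same order on 8 arrays, rapamycin gave 11, 4, 0, 1710, 2254, 4, 0, 6 and 62 genes, PP242 against rapamycin 2761, 2039, 517, 6285, 7139, 2447, 1760, 2357 and 3221, both inhibitors in the same direction 9, 4, 0, 1471, 1937, 3, 0, 5 and 58, and PP242 beyond rapamycin 2583, 1894, 501, 5618, 6110, 2296, 1646, 2206 and 3022. With array weights on 12 arrays these 4 were 2509, 7212, 2137 and 6094, and with the ratio covariate 2, 204, 2 and 193. The median signal and the deposited table each gave 1 gene between the inhibitors and 1 beyond rapamycin on 12 arrays.

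With a replicate block, PP242 against DMSO gave 0 genes on 12 arrays. On 8 arrays the replicate block gave 3982, between the inhibitors 1016, beyond rapamycin 972, and 0 for rapamycin and for both. The numbers need not pair: 5 of 12 same-number pairs correlated above 0.1 on 12 arrays (-0.78 to 0.77) and 3 of 4 on 8 arrays (-0.30 to 0.80), and 2 of 12 and 4 of 8 arrays were closest to their own number. Under this block the sterol median was -0.0231 for rapamycin and -0.10 for PP242, and the correlation of the inhibitors 0.44.

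Lists called for rapamycin were 12 with quantile normalisation, 14 on 8 arrays, with its 12-array filter and with a trend, 0 with an estimated correlation, and 0 and 6 by fry on 12 and 8 arrays. For PP242 they were 14 with quantile normalisation or weights, 13 on 8 arrays, with a trend and with the ratio covariate, 14 on 8 arrays with slide as a block or median centring, and 0 with an estimated correlation or by fry on 12 arrays. Between the inhibitors they were 0 with an estimated correlation or by fry on 12 arrays and 14 with the ratio covariate.

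The sterol median for rapamycin, -0.47 on 12 arrays, also by fry and with an estimated correlation, was -0.0638 with quantile normalisation, -0.0513 with the median signal, -0.0781 with the deposited table and 0.0844 with weights. On 8 arrays it was -0.0125, also with the 12-array filter, a trend and the covariate, -0.0585 with slide as a block, 0.0844 with weights, 0.0241 with the median signal, 0.0239 with the deposited table and -0.114 with median centring. For PP242 it was -0.30 on 12 arrays, also by fry and with an estimated correlation, -0.16 with quantile normalisation, -0.0854 with the median signal, -0.0763 with the deposited table, 0.00105 with weights and 0.0392 with the ratio covariate. On 8 arrays it was 0.0353, also with the 12-array filter or a trend, -0.0387 with slide as a block, -0.0788 with the covariate, 0.0136 with weights, 0.20 with the median signal, -0.0112 with median centring and 0.19 with the deposited table. The correlation, 0.83 on 12 arrays, was 0.51 with weights, 0.52 with the ratio covariate, and on 8 arrays 0.51, 0.44 with the 12-array filter, 0.52 with the covariate or deposited table and 0.57 with weights or the median signal.

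Leaving out 1 of 12 arrays gave 0 to 0 genes for rapamycin and for both inhibitors, 0 to 3134 for PP242, 0 to 1040 between the inhibitors and 0 to 1015 beyond rapamycin, each highest without rapamycin 3. Lists called ranged from 13 to 23 for rapamycin, 14 to 25 for PP242 and 9 to 23 between the inhibitors. The sterol median, highest without rapamycin 3 for rapamycin and without PP242 4 for the others, ranged from -0.72 to 0.0215 for rapamycin, -0.49 to 0.0394 for PP242 and -0.38 to 0.41 between them, and the correlation from 0.0607 to 0.88.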

Other observations

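Families of genes with a common name stem were tested after the data had been seen, 136 of them on the 8 arrays. With PP242 against DMSO, 15 of 18 nucleoporins (Nup) fell, with a median of -0.93 (camera adjusted p = 1.64e-07, adjusted p = 0.646 with an estimated correlation). Of 10 Mcm genes, which include the replication helicase, 8 fell (median -1.18, camera adjusted p = 0.000132), and of 14 proteasome regulatory subunits (Psmd) 9 fell (median -0.37, camera adjusted p = 0.00664). Mitochondrial ribosomal proteins of the large subunit (Mrpl) had 13 members lower and 2 higher of 49 (median -0.27, camera adjusted p = 0.00226). Zinc finger genes (Zfp) had 73 members higher and 17 lower of 276 (median 0.27, camera adjusted p = 8.97e-05, adjusted p = 0.646 with an estimated correlation). Clustered protocadherins (Pcdhb) had 7 of 20 higher (median 0.44, camera adjusted p = 0.00266), peroxins (Pex) 6 of 17 (median 0.27, camera adjusted p = 0.0388) and vacuolar sorting genes (Vps) 6 of 31 (median 0.21, camera adjusted p = 0.0427). None of these calls held with an estimated correlation, where the adjusted p was 0.646 for Mcm, Psmd, Mrpl, Pcdhb and Pex and 0.665 for Vps.

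Between PP242 and rapamycin, 11 nucleoporins were lower with PP242 (median -0.68, camera adjusted p = 9.05e-08, adjusted p = 0.397 with an estimated correlation), and 40 zinc finger genes were higher and 6 lower (median 0.20, camera adjusted p = 4.36e-05, adjusted p = 0.546 with an estimated correlation). With rapamycin against DMSO the Mrpl family had a median of -0.16 (camera adjusted p = 7.41e-05, adjusted p = 0.897 with an estimated correlation), with 0 of its 49 members passing by limma, where 2593 of all genes had an unadjusted p under 0.05.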
